A study of Mus musculus with 28 samples.

How the data were processed

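Bulk RNA of 28 mouse libraries was read by SCRB-seq, a method in which oligo-dT primers carry a sample barcode and a unique molecular identifier (UMI), the pooled cDNA is made with a template-switching oligo, and the 3′ ends of transcripts are sequenced. RNA had been isolated with a Maxwell kit. The libraries fall into control liver (n = 4), RPK tumors (n = 9), RPK;Pdk1 tumors (n = 8) and RPK;Mek1/2 tumors (n = 7), with groups taken from the labels.

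The deposited values are UMI counts per gene and library, not normalised. Per the file headers, the authors aligned reads to GRCm38 with STAR 2.7.5b and counted molecules with Drop-seq_tools 1.12 and Picard 2.18.26 against GENCODE M25, without trimming. The processing notes name mm10, R 4.02 and DESeq2 1.30.1. The column sums were checked against the library sizes in the header. Each count is a molecule of a replicated library and every comparison uses group means with their spread, so no binomial interval or count floor is given. Gene positions come from GENCODE M21 on the same build.

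The table holds 34492 genes, of which 13480 passed filterByExpr (minimum count 10, with the groups). edgeR 4.0.16 in R 4.3.3 fitted all 28 libraries at once, with TMM normalisation and quasi-likelihood F tests of contrasts between group means. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Fold changes are log2 with their SE, and CPM are TMM-scaled with the SD between libraries. Median log2 fold changes over all tested genes against control liver were 0.20 for RPK, 0.25 for RPK;Mek1/2 and 0.23 for RPK;Pdk1.

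Gene lists and the named-gene rule were fixed before the data were examined. Lists with at least 5 tested members, 31 in number, were tested by camera (limma 3.58.1) on log2 CPM (prior count 2) with the inter-gene correlation preset at 0.01, adjusted over the lists within a comparison. The same test with an estimated correlation, and fry, were run beside it. Over the 6 comparisons 86 list calls were made with the preset correlation, and 3 of them held with an estimated one. Members were counted past an adjusted p of 0.05 over all genes and adjusted over the list alone. List scores per library are means of log2(CPM + 1). Principal components were taken of the log2 CPM of the tested genes.

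Named genes were the targeted genes with Kras and Trp53, the 4 largest called rises and 4 largest called falls at an average log2 CPM of at least 5 (predicted genes passed over), 3 members with the smallest adjusted p of 7 lists, and 2 members of other called lists, of which some are left out. For the deficient tumors against control liver, 2 members of 3 lists were taken. Genes outside this rule are given as chosen after values were seen.

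Library measures (shares of mitochondrial, intergenic, intronic and other counts or reads) were compared between groups by two-sided exact permutation tests, 48 in number, with Benjamini-Hochberg adjustment. The overlap of the comparisons that share RPK libraries was set against simulated unchanged groups (20 draws) and against RPK libraries split between the comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

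Recovery was tested on simulated data with 200 of 13480 genes changed. At a 2-fold change 31% of 100 changed genes were called in RPK tumors against control liver, 46% in RPK;Mek1/2 against RPK, 56% in RPK;Pdk1 against RPK and 50% between the deficient groups. At a 4-fold change these shares were 81%, 85%, 90% and 87%, and false calls made up 5.88%, 6.43%, 2.67% and 2.14% of all calls. A list raised by 1.5-fold was called by camera, with 0 of 30 other lists. Genes were drawn independently of each other and only 1 draw was made. It therefore cannot show how often camera makes false calls on lists of correlated genes.

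Alternatives set beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, voom with sample weights, a robust fit, no count filter, and only the groups compared. Others were replicate number as a block, barcode set as a term, AT-rich or GC-rich barcodes alone (GC-rich: at least 3 of 6 bases G or C), and leaving out RPK libraries without the reporter label. The last were leaving out each library in turn, a prior count of 0.5, a pseudocount of 10, an estimated correlation and split RPK libraries. Chosen after seeing the data were leaving out the 2 shallowest RPK;Mek1/2 libraries (replicates 3 and 5), leaving out mitochondrial genes and CT010467.1, and leaving out 3 libraries under 50 CPM of Y-linked genes (control liver replicate 4, RPK;Pdk1 replicate 8 and RPK replicate 9). Subtracting the estimated exchange between barcodes and the intergenic share as a term were also chosen then. Replicate numbers do not pair the libraries across groups, since only 1 of 28 libraries correlated best with one of its own number. No library was left out of the comparisons.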

Results

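The data describe 28 mouse libraries of bulk RNA from livers and liver tumors. SCRB-seq counts 3′ ends of transcripts, with a sample barcode and a unique molecular identifier (UMI) on each oligo-dT primer, so each count is a molecule. Control liver (n = 4) held no tumor. RPK tumors (n = 9) came from a mouse model of KRAS-driven liver cancer. The other tumors were RPK tumors deficient for PDK1/AKT signaling (labelled RPK;Pdk1, n = 8) or for MEK/ERK signaling (labelled RPK;Mek1/2, n = 7), called PDK1-deficient and MEK-deficient tumors hereafter, after the stated design. Tumor-bearing mice carried AlbCreER, a tamoxifen-inducible Cre recombinase, and received tamoxifen. Control mice had the RPK genotype and no tamoxifen, and of these 4 only replicate 4 carried AlbCreER, so tumor state and treatment cannot be separated in comparisons with control liver.

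Each library held between 667610 and 3320051 UMIs. The totals ran from 1052295 to 1963047 in control liver, from 1649567 to 2480157 in RPK tumors, from 1428740 to 3320051 in PDK1-deficient tumors and from 667610 to 2759993 in MEK-deficient tumors. Mitochondrial genes took 11.4% ± 1.53 (SD, n = 4) of the counts in control liver, 6.83% ± 1.23 (n = 9) in RPK tumors, 6.82% ± 1.02 (n = 8) in PDK1-deficient tumors and 12.7% ± 3.74 (n = 7) in MEK-deficient tumors. The share in MEK-deficient tumors was higher than in RPK tumors (exact permutation test, two-sided, p = 0.000175, adjusted p = 0.0042 over 48 tests of library measures). Intergenic reads made up 12.5% ± 1.05 in control liver, 17.7% ± 2.17 in RPK tumors, 16.0% ± 1.29 in PDK1-deficient tumors and 23.2% ± 9.48 in MEK-deficient tumors, where replicate 5 reached 42.6%. The 6-base sample barcodes form an AT-rich and a GC-rich set. All 4 control livers have AT-rich barcodes, and the tumor groups split 4 to 5 (RPK), 4 to 4 (PDK1-deficient) and 4 to 3 (MEK-deficient).

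Transcripts of Map2k2, which encodes the kinase MEK2, fell in MEK-deficient tumors, while those of Map2k1 (MEK1) and of Pdpk1 (the kinase PDK1) did not pass the test in the groups named after them. Map2k2 (ENSMUSG00000035027.18) lies on GRCm38 chromosome 10, 81105915 to 81133975. It had 43.8 ± 32.7 CPM (mean ± SD, n = 7) in MEK-deficient tumors against 126 ± 35.3 (n = 9) in RPK tumors. PDK1-deficient tumors had 123 ± 42.1 (n = 8) and control liver 204 ± 71.7 (n = 4). Its log2 fold change from RPK tumors was -1.61 ± 0.30 (SE, adjusted p = 0.00878). The library labelled RPK;Mek1/2 replicate 5 had 116 CPM and the other 6 had 23.7 to 44.3, and the fold change was -2.00 without replicate 5. With fewer libraries, in AT-rich or GC-rich barcodes alone, it was -1.41 (adjusted p = 0.258) and -1.89 (adjusted p = 0.117). Map2k1 (chromosome 9, 64185770 to 64253631) gave -0.08 ± 0.20 (adjusted p = 0.906), with 44.3 ± 14.4 CPM against 46.9 ± 15.0. Pdpk1 (chromosome 17, 24073680 to 24150924) gave -0.15 ± 0.13 in PDK1-deficient against RPK tumors (adjusted p = 0.924), with 59.1 ± 7.23 CPM against 65.4 ± 14.4. Only 3′ ends were counted and the deleted part of each gene is not stated, so these values do not test whether the proteins were lost.

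The oncogene Kras and the tumor suppressor gene Trp53 were not called between tumor groups. Kras gave 0.04 ± 0.19 (adjusted p = 0.953) in MEK-deficient and 0.23 ± 0.18 (adjusted p = 0.888) in PDK1-deficient against RPK tumors, and -0.19 ± 0.19 (adjusted p = 0.71) between the deficiencies. For Trp53 the values were -0.13 ± 0.27 (adjusted p = 0.864), -0.19 ± 0.25 (adjusted p = 0.962) and 0.06 ± 0.27 (adjusted p = 0.959).

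**Figure D1:**
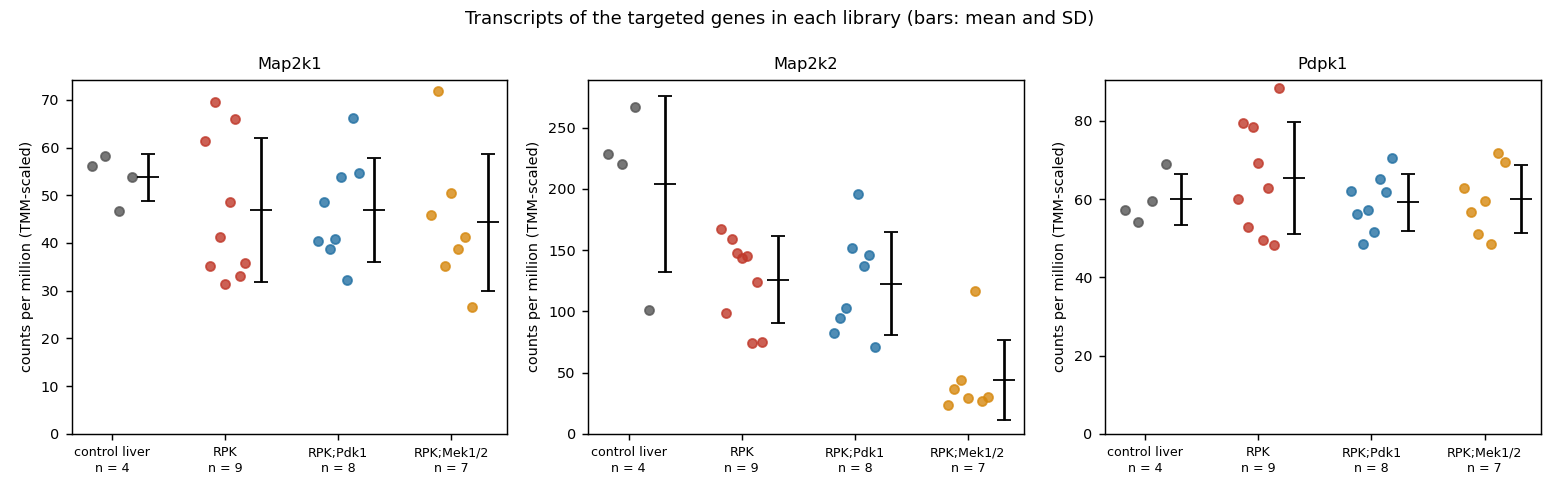
CPM (TMM-scaled, vertical axis) of Map2k1, Map2k2 and Pdpk1 in each library, by group, with the mean and SD beside the points. Of the MEK-deficient libraries, 6 lie between 23.7 and 44.3 CPM of Map2k2 and replicate 5 at 116.

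The comparison of RPK tumors with control liver asks how KRAS-driven tumors differ from the tissue they arise in. Hepatocyte transcripts fell broadly. In bulk RNA a smaller share of hepatocytes and lower expression per hepatocyte cannot be told apart. All 30 tested hepatocyte markers were lower, with a median log2 fold change of -3.12 (30 also when adjusted over the list alone). The ethanol- and drug-metabolizing enzyme Cyp2e1 dropped from 2834 ± 667 CPM (n = 4) to 172 ± 143 (n = 9), a log2 change of -4.05 ± 0.43 (adjusted p = 7.94e-09). Mttp, which loads lipid onto lipoproteins, changed by -3.15 ± 0.34 (adjusted p = 1.31e-08), Hpd, of tyrosine breakdown, by -3.96 ± 0.45 (adjusted p = 3.01e-08), and Alb, chosen after values were seen, by -3.37 ± 0.46 (adjusted p = 7.41e-07). The hepatocyte list was lower by camera (adjusted p = 1.57e-15, and adjusted p = 0.200 with an estimated correlation).

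Metabolic lists of the liver, some of which share members with the hepatocyte list (such as Cps1, Hpd and Aldob), fell with it. All 20 tested genes of the urea cycle and amino acid catabolism were lower (20 adjusted over the list alone, camera adjusted p = 1.08e-13), among them the methyltransferase Gnmt (-4.27 ± 0.45) and the glutaminase Gls2 (-3.26 ± 0.37). All 18 bile acid synthesis and transport genes were lower (18 adjusted over the list alone, adjusted p = 1.44e-13), with -4.96 ± 0.46 for the sterol hydroxylase Cyp8b1 and -4.68 ± 0.43 for the transporter Slco1a1. All 21 cholesterol synthesis genes were lower (21 adjusted over the list alone, adjusted p = 3.36e-13), with -3.50 ± 0.20 for Sc5d and -2.91 ± 0.25 for Insig1. Of 15 fatty acid synthesis genes 13 were lower (14 adjusted over the list alone, adjusted p = 1.37e-07), with -3.31 ± 0.28 for Acss2, -2.89 ± 0.25 for Fads2 and -2.33 ± 0.24 for Elovl5. Gluconeogenesis genes fell in 8 of 9 cases (8 adjusted over the list alone, adjusted p = 5.09e-05), led by Fbp1 (-3.53 ± 0.49) and Slc37a4 (-2.01 ± 0.32). Genes of both liver zones fell. Of 18 pericentral genes 12 were lower (13 adjusted over the list alone, adjusted p = 5.39e-07), such as Rgn (-4.28 ± 0.45). Of 15 periportal genes 13 were lower (13 adjusted over the list alone, adjusted p = 9.59e-07), such as Etnppl (-3.76 ± 0.42). With an estimated correlation these 7 lists had adjusted p = 0.164, 0.152, 0.0527, 0.0527, 0.200, 0.152 and 0.200 in the order given.

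The largest falls among well-expressed genes were in the hepcidin gene Hamp2 (-6.66 ± 0.87), the major urinary proteins Mup15 (-6.45 ± 0.51) and Mup1 (-6.36 ± 0.51), and the plasma protein gene A1bg (-6.44 ± 0.81). Hamp2 and A1bg rest on control replicate 4: without it the changes were -0.87 (adjusted p = 0.204) and -1.03. That library was also low in Y-linked genes (32.3 CPM, against 104 to 133 in the other control livers). The falls of Hamp2 and A1bg are therefore not shown to belong to the tumors.

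Cell division, ERK target genes, biliary markers and the markers of several stromal and immune cells rose in RPK tumors. Of 30 cell division genes, 28 were higher (29 adjusted over the list alone), with a median log2 fold change of 1.42 and a camera adjusted p = 6.94e-11 (adjusted p = 0.164 with an estimated correlation). Mki67, a marker of cycling cells, rose from 22.6 ± 4.07 CPM (n = 4) to 110 ± 35.5 (n = 9), the topoisomerase Top2a rose by 2.47 ± 0.33 (adjusted p = 3.79e-07) and Ube2c by 1.93 ± 0.25. Among 22 ERK pathway target genes, 16 were higher and 1 lower (18 and 1 adjusted over the list alone), with a median of 1.02 (adjusted p = 6.48e-05, and adjusted p = 0.104 with an estimated correlation). The cyclin gene Ccnd1 rose by 1.57 ± 0.26 (adjusted p = 1.53e-05, 550 ± 132 CPM against 186 ± 34.6), the urokinase receptor gene Plaur by 1.33 ± 0.25 and the ERK phosphatase gene Dusp5 by 1.97 ± 0.38. Kras itself rose by 0.91 ± 0.24 (adjusted p = 0.00253, 168 ± 40.0 CPM against 89.9 ± 4.97), while Trp53 gave 0.57 ± 0.35 (adjusted p = 0.181).

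Of 23 tested biliary markers, 11 were higher and none lower (12 and 0 adjusted over the list alone), with a median log2 fold change of 1.27. The camera adjusted p was 0.00291, and adjusted p = 0.397 with an estimated correlation. Bicc1, a gene of bile duct and kidney epithelium, rose by 1.92 ± 0.29 (adjusted p = 4.05e-06). The transcription factor genes Sox4 and Sox9 rose by 1.66 ± 0.35 (adjusted p = 0.000318) and 1.27 ± 0.33 (adjusted p = 0.00278). Sox9 had 186 ± 34.4 CPM against 77.2 ± 9.01 in control liver. Classical duct markers, chosen after values were seen, gave 1.38 ± 0.50 for Krt19 (adjusted p = 0.0252) and 1.58 ± 0.59 for Krt7 (adjusted p = 0.0301). They gave 0.88 ± 0.29 for Spp1 (adjusted p = 0.0142) and 1.49 ± 0.70 for Epcam (adjusted p = 0.0835). The calls of Krt19 and Krt7 were lost without any one of the 4 control livers or RPK replicate 1, with changes of 1.09 and 1.22 without the last. They were lost too with AT-rich barcodes alone (1.16, adjusted p = 0.0992, and 1.24, adjusted p = 0.0838). That of Spp1 was lost without control replicate 1, 2 or 3 (0.81, 0.79 and 0.73).

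**Figure D2:**
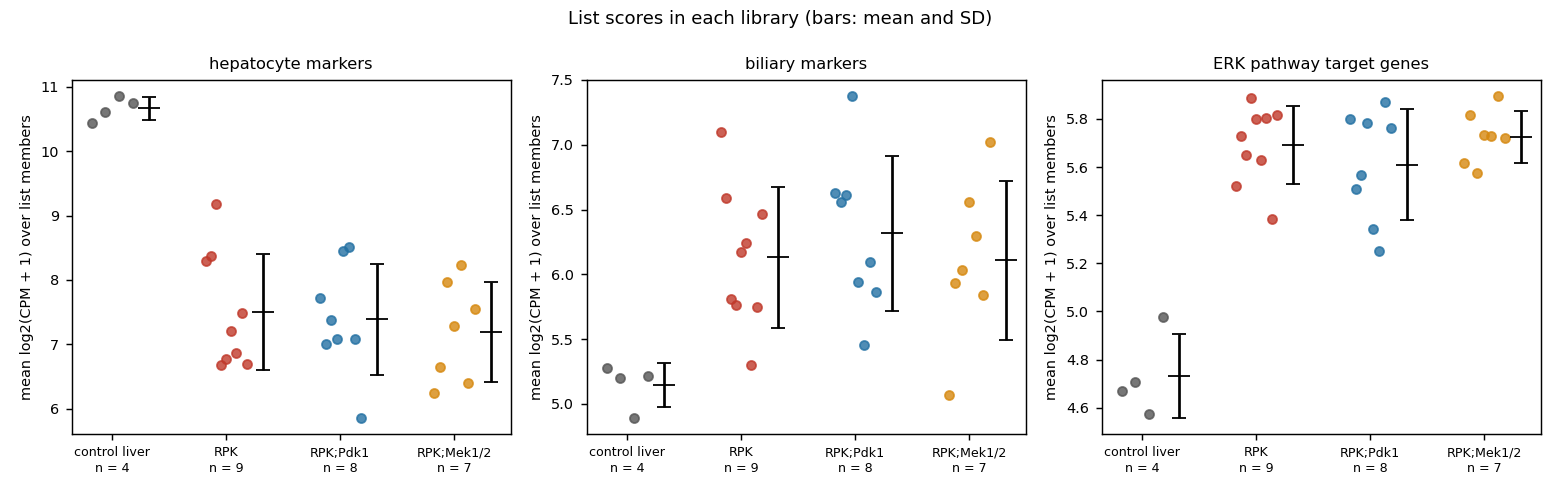
List scores (mean log2(CPM + 1) over list members, vertical axis) of hepatocyte markers, biliary markers and ERK pathway target genes in each library, by group, with the mean and SD beside the points. The mean hepatocyte score is 10.66 in control liver and 7.19 to 7.51 in the tumor groups, and the mean ERK score is 4.73 in control liver and 5.61 to 5.73 in the tumor groups.

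Stromal markers rose as well. Of 23 fibroblast and stellate cell markers 16 were higher and 1 lower (16 and 1 adjusted over the list alone). Their median was 1.54 (adjusted p = 2.32e-05, and adjusted p = 0.225 with an estimated correlation). Fbn1 rose by 1.79 ± 0.25, Timp1 by 1.93 ± 0.29 and Col5a1 by 1.83 ± 0.29. Fstl1, a secreted glycoprotein of mesenchymal cells, had one of the largest rises (2.61 ± 0.33, adjusted p = 2.45e-07, 364 ± 105 CPM against 59.6 ± 9.17), beside the linker histone H1f5 (2.76 ± 0.51) and Slfn9 (2.59 ± 0.39). Of 15 epithelial-mesenchymal transition genes 10 were higher and 1 lower (13 and 1 adjusted over the list alone), such as Mmp14 (1.84 ± 0.34) and Vim (1.71 ± 0.33). That list had adjusted p = 0.0038, and adjusted p = 0.218 with an estimated correlation. YAP/TEAD target genes rose in 12 of 19 cases (13 adjusted over the list alone, adjusted p = 0.00153, and adjusted p = 0.164 with an estimated correlation), such as Myof (1.41 ± 0.25) and Ccn2 (2.01 ± 0.37). Notch pathway genes rose in 5 of 14 cases (4 adjusted over the list alone, adjusted p = 0.0376, and adjusted p = 0.200 with an estimated correlation), such as Hes1 (0.90 ± 0.23) and Nrarp (1.32 ± 0.36). The Notch call was lost without control replicate 3 (adjusted p = 0.0638).

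Of the immune lists, macrophage markers rose in 12 of 18 cases (14 adjusted over the list alone, adjusted p = 0.00291), such as Ctss (1.70 ± 0.36) and Ccr2 (2.31 ± 0.54). Neutrophil markers rose in 11 of 14 cases (13 adjusted over the list alone, adjusted p = 0.0072), such as Il1r2 (2.34 ± 0.56) and Mmp8 (2.38 ± 0.64). Antigen-presenting cell genes rose in 7 of 9 (7 adjusted over the list alone, adjusted p = 0.0267), such as H2-DMb1 (1.72 ± 0.44) and H2-DMa (1.55 ± 0.45). With an estimated correlation these 3 lists had adjusted p = 0.407, 0.407 and 0.490. The FOXO-induced list, read here for the AKT branch of the pathway, went both ways, with 4 higher and 3 lower of 20 (2 and 3 adjusted over the list alone, adjusted p = 0.974). Klf15 was lower (-3.02 ± 0.38), as was Erbb3 (-1.69 ± 0.39), and Pik3ip1 was higher (1.43 ± 0.41).

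In all, 6021 of 13480 tested genes differed between RPK tumors and control liver (2928 higher, 3093 lower, edgeR adjusted p under 0.05). The number of higher genes rests on the control livers: it was 1745 without control liver replicate 2 and 1654 without replicate 3, with 3046 and 2957 lower. The biliary, hepatocyte and ERK lists kept their direction and call with AT-rich barcodes alone (adjusted p = 0.0214, 1.34e-17 and 0.000200), the set that holds every control liver.

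The hepatocyte, biliary and ERK lists were also called in both deficient tumor groups against control liver. In MEK-deficient tumors 30 of 30 hepatocyte markers were lower (30 adjusted over the list alone, median -3.50, adjusted p = 4.44e-16). In these tumors 10 of 23 biliary markers were higher (10 adjusted over the list alone, adjusted p = 0.00538). Of 22 ERK target genes 16 were higher and 1 lower (17 and 1 adjusted over the list alone, median 1.17, adjusted p = 0.000135). In PDK1-deficient tumors 30 of 30 hepatocyte markers were lower (30 adjusted over the list alone, median -3.08, adjusted p = 1.60e-16). There 15 of 23 biliary markers were higher (15 adjusted over the list alone, adjusted p = 0.000592). Of 22 ERK target genes 13 were higher and 1 lower (14 and 1 adjusted over the list alone, median 0.98, adjusted p = 0.000324). With an estimated correlation the hepatocyte, biliary and ERK lists had adjusted p = 0.211, 0.422 and 0.129 in MEK-deficient tumors, and adjusted p = 0.188, 0.351 and 0.125 in PDK1-deficient tumors. Bicc1 rose by 1.84 ± 0.30 in MEK-deficient tumors and by 2.04 ± 0.30 in PDK1-deficient tumors, Sox4 by 2.01 ± 0.37 and 1.78 ± 0.36, and Ccnd1 by 1.45 ± 0.27 and 1.60 ± 0.26. Plaur rose by 1.32 ± 0.26 in MEK-deficient tumors, and Spred1, a feedback inhibitor of the pathway, by 1.05 ± 0.18 in PDK1-deficient tumors. Cyp2e1 changed by -4.34 ± 0.47 and -4.98 ± 0.46, Mttp by -3.33 ± 0.38 in MEK-deficient tumors, and Cyp3a11 by -4.59 ± 0.50 in PDK1-deficient tumors. In PDK1-deficient tumors 14 of 15 fatty acid synthesis genes were lower (14 adjusted over the list alone, adjusted p = 7.47e-08). All 21 cholesterol synthesis genes were lower there (21 adjusted over the list alone, adjusted p = 7.92e-13). These 2 lists stayed called, each with adjusted p = 0.0454 with an estimated correlation. In total 6636 genes differed from control liver in MEK-deficient tumors (3484 higher, 3152 lower) and 5894 in PDK1-deficient tumors (2959 higher, 2935 lower). Without control liver replicate 2 or 3 the higher genes numbered 2192 and 2079 in MEK-deficient tumors. In PDK1-deficient tumors they numbered 1891, 1571, 1530 and 1836 without control liver replicate 1, 2, 3 or 4.

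The comparison of MEK-deficient with RPK tumors asks which parts of the tumor program depend on MEK/ERK signaling. Fibroblast and stellate cell markers were lower as a list in MEK-deficient tumors, with a median log2 fold change of -0.56 (camera adjusted p = 8.94e-10, and adjusted p = 0.662 with an estimated correlation). Their mean score fell from 6.97 ± 0.27 (n = 9) to 6.42 ± 0.39 (n = 7). None of the 23 passed among all genes, and 11 passed, all lower, when adjusted over the list alone. Among them were Fbn1 (-0.80 ± 0.18, adjusted p = 0.0512 among all genes), Timp1 (-0.90 ± 0.22, adjusted p = 0.0622) and Acta2, a gene of contractile fibroblasts (-1.21 ± 0.35, adjusted p = 0.132). Fstl1 fell by 1.17 ± 0.25 (adjusted p = 0.0256, 162 ± 53.8 CPM against 364 ± 105). No difference was called for ERK pathway target genes (0 of 22, 0 adjusted over the list alone, median 0.01, camera adjusted p = 0.703). Nor was one called for biliary markers (0 of 23, 1 higher adjusted over the list alone, median 0.11, adjusted p = 0.755).

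Among ERK target genes the smallest adjusted p belonged to Dusp4 (0.76 ± 0.36, adjusted p = 0.357), Dusp5 (-0.54 ± 0.27, adjusted p = 0.376) and Spry2 (0.44 ± 0.22, adjusted p = 0.383). The mean ERK score was 5.73 ± 0.11 (n = 7) in MEK-deficient and 5.69 ± 0.16 (n = 9) in RPK tumors. Biliary genes with the smallest adjusted p were Cd24a (0.89 ± 0.25, adjusted p = 0.114), Mmp7 (-1.42 ± 0.62, adjusted p = 0.314) and Cdh6 (0.87 ± 0.38, adjusted p = 0.317). Krt19, chosen after values were seen, gave -0.37 ± 0.39. The biliary list was higher among AT-rich barcodes (adjusted p = 0.000344) and lower among GC-rich ones (adjusted p = 6.07e-05). Hepatocyte markers had a median of -0.45 and a camera adjusted p = 0.0136 (0 of 30 called, 0 adjusted over the list alone, and adjusted p = 0.759 with an estimated correlation). Among them Kng1 was at -0.84 ± 0.49, Gc at -0.69 ± 0.42 and Fgb at -0.78 ± 0.50. That call ended without RPK replicate 1, 2 or 3 (adjusted p = 0.0946, 0.186 and 0.475) or RPK;Mek1/2 replicate 1, 2 or 6 (adjusted p = 0.309, 0.115 and 0.210). The direction turned among AT-rich barcodes (adjusted p = 0.0733) while GC-rich ones gave adjusted p = 7.27e-09.

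Other lists that camera called lower in MEK-deficient than in RPK tumors were interferon-stimulated genes (median -0.77, adjusted p = 5.38e-07) and acute-phase genes (-0.86, adjusted p = 4.52e-05). So were macrophage markers (-0.37, adjusted p = 8.75e-05), endothelial markers (-0.51, adjusted p = 0.000899) and neutrophil markers (-0.54, adjusted p = 0.00109). No member of these 5 lists passed, among all genes or adjusted over the list alone, and each had adjusted p = 0.724 with an estimated correlation. Within AT-rich barcodes the interferon, acute-phase, endothelial and neutrophil calls were lost (adjusted p = 0.0733, 0.340, 0.154 and 0.0733), and within GC-rich ones the macrophage call was (adjusted p = 0.418). Members of the 5 lists with the smallest adjusted p included Stat1 (-0.80 ± 0.27), the acute-phase protein gene Saa2 (-1.68 ± 0.62), the complement gene C1qb (-0.58 ± 0.23) and the granule protein gene Ltf (-1.83 ± 0.68). Pancreatic acinar markers were called higher (7 of 7 adjusted over the list alone, 0 among all genes, median 3.92, adjusted p = 0.0269, and adjusted p = 0.724 with an estimated correlation). This rests on RPK;Mek1/2 replicate 2, without which the list had adjusted p = 0.887. The call was also lost without RPK replicate 1 or 2 (adjusted p = 0.0685 and 0.0814) or RPK;Mek1/2 replicate 5 (adjusted p = 0.0542), with exchange between barcodes subtracted (adjusted p = 0.142) and with the intergenic share as a term (adjusted p = 0.0637). Within AT-rich barcodes the direction turned (adjusted p = 0.987). Cela3b gave 4.24 ± 1.02 (adjusted p = 0.0602) and Cpb1 3.97 ± 0.96 (adjusted p = 0.0622). Cell division (0 of 30, median -0.04, adjusted p = 0.482) included Cdc20 at -0.64 ± 0.26, Cdca8 at -0.30 ± 0.21 and Cenpf at -0.33 ± 0.24. That list was lower within AT-rich barcodes (adjusted p = 2.50e-05) and higher within GC-rich ones (adjusted p = 0.00240). FOXO-induced genes (0 of 20, 1 higher adjusted over the list alone, adjusted p = 0.0847) included Gadd45a at 0.92 ± 0.21 (adjusted p = 0.0533), Trib1 at 0.50 ± 0.20 and Cited2 at 0.40 ± 0.20. Fatty acid synthesis (0 of 15, adjusted p = 0.463) included Thrsp at -0.96 ± 0.54, Elovl6 at -0.36 ± 0.22 and Acly at -0.30 ± 0.19.

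In total 40 of 13480 genes differed between MEK-deficient and RPK tumors (33 higher, 7 lower). After Map2k2, the falls were led by the ribosomal protein gene Rplp1 (-1.26 ± 0.18, adjusted p = 0.000416, 803 ± 260 CPM against 1926 ± 336). The predicted gene Gm11942, a copy of Rplp1 chosen after values were seen, rose by 4.56 ± 0.25 (adjusted p = 1.49e-13). It had at least 439 CPM in each of the 7 MEK-deficient libraries and at most 51.7 in RPK tumors. The largest rises were in Nrf1, a transcription factor gene of mitochondrial biogenesis (2.16 ± 0.41, adjusted p = 0.00965), and in Hoxb2 (1.98 ± 0.36, adjusted p = 0.0073). Next were the kinase gene Map3k10 (1.85 ± 0.37, adjusted p = 0.0144) and Nav2 (1.73 ± 0.37, adjusted p = 0.0296). Of mitochondrial transcripts, also chosen after values were seen, 7 rose, such as mt-Cytb by 1.39 ± 0.23 and mt-Nd1 by 1.29 ± 0.22. The call of mt-Nd5 was lost without RPK replicate 3 or 6 (1.08 and 1.06). That of mt-Rnr1 was lost without control liver replicate 1 (1.14), RPK;Pdk1 replicate 1, 2 or 4 (1.17 each), RPK replicate 1, 3, 4, 5, 6, 7 or 8 (1.11 to 1.18) or RPK;Mek1/2 replicate 3 or 5 (1.11 and 0.80).

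The count of 40 moved by over 1.5 times without RPK replicate 2 (62), 3 (24), 6 (21), 8 (22) or 9 (74). It did so too without RPK;Mek1/2 replicate 1 (113) or 4 (116) or RPK;Pdk1 replicate 8 (78). The 33 higher genes became 20 without RPK replicate 1 and 19 without RPK;Mek1/2 replicate 5. Nav2 lost its call without RPK replicate 1, 3, 6, 7 or 8 or RPK;Mek1/2 replicate 3, 5 or 6, with 1.34 at the lowest. Fstl1 lost it without RPK replicate 6 or 8 or RPK;Mek1/2 replicate 3, 5, 6 or 7, with -1.06 without RPK;Mek1/2 replicate 6. Map3k10 lost it without RPK;Mek1/2 replicate 5 (1.44). Within AT-rich or GC-rich barcodes alone 2 genes and 1 gene were called. With the intergenic share as a term 13 were called, with none of Nrf1 (1.39), Hoxb2 (1.22) and Map3k10 (1.02) among them. These 3 lost their calls also without the 2 shallowest RPK;Mek1/2 libraries (adjusted p = 0.0702, 0.0717 and 0.132).

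The comparison of PDK1-deficient with RPK tumors asks the same of PDK1/AKT signaling. Neutrophil markers were lower in PDK1-deficient tumors, with a median log2 fold change of -1.63 (camera adjusted p = 1.82e-17, and adjusted p = 0.0337 with an estimated correlation). Their mean score was 3.24 ± 0.27 (n = 8), close to the 3.06 ± 0.20 (n = 4) of control liver, against 4.34 ± 0.84 (n = 9) in RPK tumors. Of 14 tested markers none passed among all genes and 12 passed, all lower, when adjusted over the list alone. Retnlg gave -2.08 ± 0.48 (adjusted p = 0.122, 7.69 ± 2.63 CPM against 32.4 ± 34.1) and Camp, an antimicrobial granule peptide, -2.62 ± 0.63 (adjusted p = 0.148). The list was lower within AT-rich and within GC-rich barcodes (adjusted p = 1.67e-07 and 2.15e-08), and fry, which tests whether the members move one way on balance, gave adjusted p = 0.047.

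Other lists that camera called lower were fibroblast and stellate cell markers (median -0.32, adjusted p = 3.33e-07, 3 lower adjusted over the list alone), macrophage markers (-0.42, adjusted p = 4.38e-07) and epithelial-mesenchymal transition genes (-0.34, adjusted p = 3.46e-06). These had adjusted p = 0.428, 0.428 and 0.159 with an estimated correlation. Timp1 gave -0.99 ± 0.21 (adjusted p = 0.0755, 220 ± 63.9 CPM against 437 ± 122). Lox, which cross-links collagen, gave -0.85 ± 0.24, Fbn1 -0.53 ± 0.17, the scavenger receptor gene Msr1 -0.86 ± 0.26, Mafb -0.55 ± 0.21, Tgfbi -0.84 ± 0.27 and Sparc -0.52 ± 0.21. The fibroblast call was not seen within GC-rich barcodes (adjusted p = 0.391). Endothelial markers (median -0.38, adjusted p = 8.25e-05), glycolysis and hypoxia genes (-0.15, adjusted p = 0.00215), Kupffer cell markers (-0.61, adjusted p = 0.00365) and erythroid markers (-0.60, adjusted p = 0.00794) were called lower. Each had adjusted p = 0.551 with an estimated correlation. Interferon-stimulated genes (-0.24, adjusted p = 0.00253), cell division genes (-0.17, adjusted p = 0.0123), and the bile acid, urea cycle and mucin lists (-0.46, -0.27 and -0.32, adjusted p = 0.0241 each) were called lower. Each had adjusted p = 0.777 with an estimated correlation. Members of these lists with the smallest adjusted p included Emcn (-0.80 ± 0.27), Adm (-1.10 ± 0.38), Bub1 (-0.55 ± 0.25), Ccnb1 (-0.48 ± 0.27), Aurkb (-0.37 ± 0.24), Cyp7a1 (-1.15 ± 0.53), Arg1 (-0.70 ± 0.28) and Gkn1 (-2.33 ± 0.61). No member of these 12 lists passed among all genes, and besides the 3 fibroblast markers only mucin genes passed adjusted over the list alone (1 higher, 2 lower). The cell division call was not seen within GC-rich barcodes, where the list was higher (adjusted p = 0.0386). The endothelial call was lost within AT-rich barcodes (adjusted p = 0.213), the glycolysis and erythroid calls within GC-rich ones (adjusted p = 0.349 and 0.0745), and the mucin call in each set (adjusted p = 0.274 and 0.308). Within AT-rich barcodes 4 lists turned upward: Kupffer cell (adjusted p = 0.286), interferon (adjusted p = 0.825), bile acid (adjusted p = 0.211) and urea cycle genes (adjusted p = 0.0439).

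Several of these calls in PDK1-deficient against RPK tumors rest on single libraries or on the processing. The bile acid call was lost without RPK;Pdk1 replicate 2, 4, 7 or 8 (adjusted p = 0.102, 0.0724, 0.107 and 0.413) or RPK replicate 1, 2 or 3 (adjusted p = 0.260, 0.171 and 0.851). It was lost too without a count filter (adjusted p = 0.0871), with voom (0.306), without the 3 libraries low in Y-linked genes (0.116), with exchange between barcodes subtracted (0.347) and with the intergenic share as a term (0.129). The urea cycle call was lost without the same 7 libraries (adjusted p = 0.0977, 0.106, 0.0977, 0.560, 0.144, 0.282 and 0.873), and in the last 4 of those settings (adjusted p = 0.414, 0.292, 0.162 and 0.162). The mucin call was lost without RPK;Pdk1 replicate 2, 6 or 7 (adjusted p = 0.0700, 0.234 and 0.156) or RPK replicate 1, 5 or 9 (adjusted p = 0.183, 0.177 and 0.150). It was lost too with only the groups compared (adjusted p = 0.158), without the 2 shallowest RPK;Mek1/2 libraries (0.0837), without the 3 low in Y-linked genes (0.291) and with the intergenic term (0.0745). The cell division call was lost without RPK;Pdk1 replicate 4 or 6 (adjusted p = 0.104 and 0.213) or RPK replicate 4, 5 or 7 (adjusted p = 0.0892, 0.0918 and 0.288), and without the RPK libraries lacking the reporter (adjusted p = 0.644). The interferon call was lost without RPK;Pdk1 replicate 4 (adjusted p = 0.113) or RPK replicate 1 or 3 (adjusted p = 0.105 and 0.0578). The erythroid call was lost without RPK;Pdk1 replicate 7 (adjusted p = 0.0764) or RPK replicate 3 or 6 (adjusted p = 0.0528 and 0.0566), and the Kupffer cell call without RPK replicate 3 (adjusted p = 0.150).

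**Figure D3:**
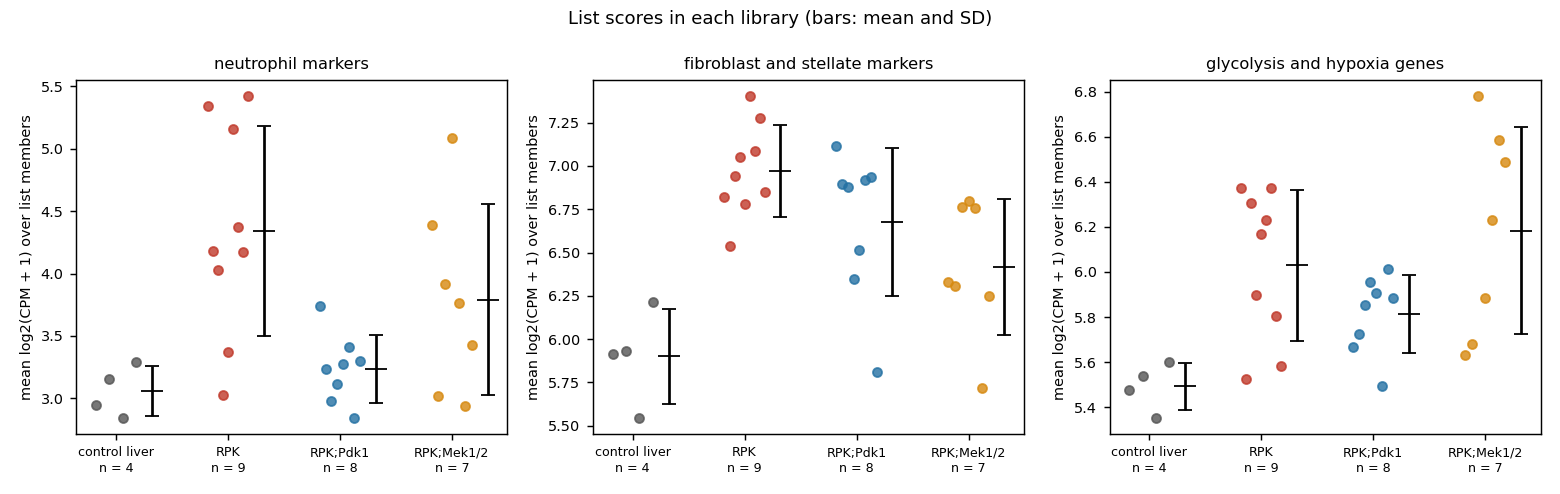
List scores (mean log2(CPM + 1) over list members, vertical axis) of neutrophil markers, fibroblast and stellate cell markers, and glycolysis and hypoxia genes in each library, by group, with the mean and SD beside the points. The mean neutrophil score is 4.34 in RPK tumors, 3.79 in MEK-deficient tumors, 3.24 in PDK1-deficient tumors and 3.06 in control liver.

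No difference was called in PDK1-deficient against RPK tumors for biliary markers (0 of 23, 0 adjusted over the list alone, median 0.27, adjusted p = 0.108) or hepatocyte markers (0 of 30, 0 adjusted over the list alone, median -0.15, adjusted p = 0.236). The same held for ERK target genes (0 of 22, 0 adjusted over the list alone, median -0.13, adjusted p = 0.209) and FOXO-induced genes (0 of 20, 0 adjusted over the list alone, median 0.07, adjusted p = 0.941). Barcode sets differed here too: biliary markers gave adjusted p = 0.993 within AT-rich and, higher, 0.000372 within GC-rich barcodes, and hepatocyte markers were higher within AT-rich (adjusted p = 0.00505) and lower within GC-rich ones (adjusted p = 1.94e-05). Values with the smallest adjusted p were, for biliary markers, Muc1 (-1.03 ± 0.45), Hnf1b (0.42 ± 0.27) and Cdh6 (0.55 ± 0.37), and for hepatocyte markers Cyp2e1 (-0.94 ± 0.37), Cyp3a11 (-0.91 ± 0.40) and Hnf4a (0.43 ± 0.24). Among ERK targets they were Epha4 (1.16 ± 0.36), Dusp5 (-0.46 ± 0.25) and Dusp4 (-0.55 ± 0.36), and among FOXO-induced genes Ccng2 (-0.44 ± 0.26), Cdkn1b (0.23 ± 0.15) and Foxo1 (0.23 ± 0.17). Fatty acid synthesis genes (0 of 15, adjusted p = 0.896, with a median of 0.11 against a downward camera sign) included Acly (-0.47 ± 0.18), Thrsp (-0.93 ± 0.50) and Scd1 (-0.59 ± 0.34).

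By edgeR 4 genes differed between PDK1-deficient and RPK tumors, with 936 at an unadjusted p under 0.05, while DESeq2 called 30 and voom 7. The lipid transporter gene Abca3 rose by 1.07 ± 0.21 (adjusted p = 0.0476, 65.1 ± 23.3 CPM against 30.8 ± 9.01). The other 3, chosen after values were seen, were the predicted gene Gm6475 (-2.48 ± 0.34), Npw (3.06 ± 0.50) and the mast cell tryptase gene Tpsab1 (3.62 ± 0.70). All 4 lie on chromosome 17, which also carries Pdpk1: Abca3 at 24351950 to 24410201, Npw at 24657330 to 24658457, Tpsab1 at 25343245 to 25345562 and Gm6475 at 3312250 to 3314185. Abca3 lost its call in 21 of 28 leave-one-out fits (0.92 to 1.18 over all 28). It kept it only without control liver replicate 4, RPK;Pdk1 replicate 1, 2, 7 or 8, RPK replicate 9 or RPK;Mek1/2 replicate 5. Tpsab1 gave 1.39 (adjusted p = 0.207) without RPK;Pdk1 replicate 5. It lost its call in 18 other fits, with 3.50 or more, and kept it without control liver replicate 4, RPK;Mek1/2 replicate 5 or any other RPK;Pdk1 library.

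MEK-deficient and PDK1-deficient tumors were also compared with each other, as the direct test of whether the deficiencies differ. Glycolysis and hypoxia genes were higher in MEK-deficient tumors (2 of 20 called, 7 higher adjusted over the list alone, median 0.42, camera adjusted p = 0.00196, and adjusted p = 0.973 with an estimated correlation). The angiogenic factor Vegfa had 516 ± 579 CPM (n = 7) against 151 ± 28.6 (n = 8), a change of 1.77 ± 0.37 (adjusted p = 0.0185). The vasodilator peptide gene Adm gave 1.71 ± 0.41 (adjusted p = 0.0495). The plasminogen activator inhibitor gene Serpine1 rose by 1.86 ± 0.43 (adjusted p = 0.0376), and the fibroblast gene Dpt fell by 1.85 ± 0.43 (adjusted p = 0.0376). Vegfa, Adm and Serpine1 rest on RPK;Mek1/2 replicate 3: without it they gave 1.04 (adjusted p = 0.12), 1.18 (adjusted p = 0.233) and 1.23 (adjusted p = 0.209). Serpine1 lost its call also without RPK;Pdk1 replicate 1, 2, 3, 4, 5 or 7 (1.90, 1.84, 1.87, 1.82, 1.87 and 1.79) or RPK;Mek1/2 replicate 7 (1.65). Dpt lost it without RPK;Pdk1 replicate 1, 2, 3 or 4 (-1.66, -1.86, -1.60 and -1.86) or RPK;Mek1/2 replicate 1, 3, 6 or 7 (-1.83, -1.75, -1.71 and -1.79). Adm lost it in 17 further leave-one-out fits (1.64 to 1.77), keeping it only without control liver replicate 2, RPK;Pdk1 replicate 5 or 8, RPK replicate 2, 3, 7 or 9, or RPK;Mek1/2 replicate 1, 2 or 4.

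Neutrophil markers were higher in MEK-deficient than in PDK1-deficient tumors (2 of 14 adjusted over the list alone, none among all genes, median 0.82, adjusted p = 0.0144), with 2.12 ± 0.60 for Ngp and 2.12 ± 0.66 for Camp. That call was lost without RPK;Mek1/2 replicate 1 or 4 (adjusted p = 0.0726 and 0.207). Immediate-early genes were also higher (median 0.29, adjusted p = 0.0385), with Dusp1 at 0.77 ± 0.29. Acute-phase genes (median -0.61, adjusted p = 0.0168), with Il1rn at -1.32 ± 0.40, and interferon-stimulated genes (-0.51, adjusted p = 0.0319), with Stat2 at -0.44 ± 0.22, were lower. Of these 3 lists 1 acute-phase gene passed, lower, adjusted over the list alone. Each of these 4 lists had adjusted p = 0.973 with an estimated correlation, and none of them, nor the glycolysis list (adjusted p = 0.308), was called within GC-rich barcodes. The immediate-early call was lost without RPK;Pdk1 replicate 6, 7 or 8 (adjusted p = 0.141, 0.0722 and 0.0794), RPK replicate 2 or 3 (adjusted p = 0.0567 and 0.0516) or RPK;Mek1/2 replicate 3, 4, 5, 6 or 7 (adjusted p = 0.167, 0.0750, 0.0507, 0.127 and 0.0607). It was lost too without a count filter (adjusted p = 0.0614), with a replicate block (0.0508), voom (0.179) or the intergenic term (0.106), and without the 2 shallowest RPK;Mek1/2 libraries (0.223) or the 3 libraries low in Y-linked genes (0.0782). The acute-phase call was lost without RPK;Pdk1 replicate 6 (adjusted p = 0.191) or RPK;Mek1/2 replicate 1, 2 or 6 (adjusted p = 0.0947, 0.0769 and 0.142), and with exchange subtracted (adjusted p = 0.0583). The interferon call was lost without RPK;Pdk1 replicate 1, 5 or 6 (adjusted p = 0.184, 0.413 and 0.121) or RPK;Mek1/2 replicate 1, 2, 6 or 7 (adjusted p = 0.0823, 0.0769, 0.128 and 0.153).

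Biliary markers (0 of 23, 0 adjusted over the list alone, median -0.07, adjusted p = 0.577) and hepatocyte markers (0 of 30, 0 adjusted over the list alone, median -0.28, adjusted p = 0.233) were not called between the deficiencies. Nor were ERK target genes (0 of 22, 1 higher and 1 lower adjusted over the list alone, median 0.24, adjusted p = 0.306) or FOXO-induced genes (0 of 20, 3 higher adjusted over the list alone, median 0.19, adjusted p = 0.18). Within AT-rich barcodes the ERK list was called higher in MEK-deficient tumors (adjusted p = 0.0210), and within GC-rich ones it was not (adjusted p = 0.941). Biliary markers were higher within AT-rich (adjusted p = 8.76e-06) and lower within GC-rich barcodes (adjusted p = 2.49e-07). Biliary and hepatocyte values with the smallest adjusted p included Cd24a (0.81 ± 0.26), Krt7 (-0.87 ± 0.47), Hnf4a (-0.69 ± 0.26, adjusted p = 0.271), and Apoa1 (-0.91 ± 0.46). In the ERK and FOXO lists they included Epha4 (-1.66 ± 0.42, adjusted p = 0.0667), Dusp4 (1.31 ± 0.38, adjusted p = 0.131), Gadd45a (0.75 ± 0.22) and Ccng2 (0.87 ± 0.27). In fatty acid synthesis (adjusted p = 0.816) Fasn gave -0.49 ± 0.22, in cell division (adjusted p = 0.474) Bub1 gave 0.78 ± 0.26, and among fibroblast markers (1 of 23 lower, adjusted p = 0.114) Des gave -1.43 ± 0.55. In total 64 genes differed (53 higher, 11 lower in MEK-deficient tumors). Rises were led by Hoxb2 (2.75 ± 0.39, adjusted p = 0.000231), Nrf1 (2.62 ± 0.44, adjusted p = 0.00172) and Map3k10 (2.43 ± 0.39, adjusted p = 0.00105), and falls by Map2k2 (-1.57 ± 0.30, adjusted p = 0.00913), Rplp1 (-1.21 ± 0.18, adjusted p = 0.000438) and Slfn9 (-1.20 ± 0.25, adjusted p = 0.0185). The count of 64 moved by over 1.5 times without RPK;Mek1/2 replicate 3 (31) or 4 (116) or RPK;Pdk1 replicate 1 (40), 2 (38), 3 (42), 4 (41), 5 (40) or 8 (188). The 53 higher genes became 34 without RPK;Mek1/2 replicate 7, and the 11 lower ones 18 without RPK;Pdk1 replicate 7. Slfn9 lost its call without RPK;Mek1/2 replicate 3 (-1.08) or 7 (-1.11). Library quality differed between these groups as well (exact permutation tests). MEK-deficient libraries had more intergenic reads (23.2% against 16.0%, adjusted p = 0.0403) and fewer mapped reads (63.9% against 69.8%, adjusted p = 0.0132). They also had fewer UMIs per exonic read (30.8% against 41.2%, adjusted p = 0.0161). Quality and deficiency are therefore not separated for the genes called here, Hoxb2, Nrf1 and Map3k10 included.

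The changes of MEK-deficient and PDK1-deficient tumors against RPK tumors correlated across the 13480 genes (Pearson r = 0.416), which are not independent replicates. Both comparisons use the same 9 RPK libraries. Simulated groups without any change, with the RPK libraries drawn anew each time as well, gave a mean r of 0.440 (0.417 to 0.459 over 20 draws). Drawing the RPK libraries anew was added after the result of a first simulation without it was seen. The covariance was 0.0747 against a mean of 0.0428 in the simulated groups. Real changes add variance that can lower r, so r alone does not show whether the deficiencies share changes. No gene was called in both comparisons by edgeR. At an unadjusted p under 0.05, 111 genes were higher in both, 106 lower in both and 12 opposite, against 69, 53.95 and 1 in the simulated groups. Independent comparisons with these numbers of genes would share 39.3 higher and 23.0 lower in the data and 8.34 and 9.48 in the simulated groups, so the raw counts do not show more sharing than the simulation. With the RPK libraries split between the comparisons, r averaged 0.110 (-0.003 to 0.173), and 27.75, 27.7 and 29 genes were shared higher, shared lower and opposite.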

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

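Chosen after results were seen were the tests of genes near Pdpk1, of levels shared by library-specific genes, of the copies of Rplp1 and of what other splits part, and the settings with exchange subtracted or an intergenic term. Dixon's test marks a library whose gap to its nearest neighbor is a large part of its group's range, and chance marks about 1 in 20 groups. It marked 6 of 32 group measures (1.6 by chance), 7 of 128 list scores (6.4 by chance) and 49 of 564 named gene values (28.2 by chance).

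Library RPK;Mek1/2 replicate 5 stood apart from its group in intergenic reads (42.64%), in UMIs per exonic read (13.55%), in the mitochondrial share (20.4%) and in the share of CT010467.1 (13.6%). It was also apart in Map2k2 (6.88, on the log2(CPM + 1) scale used for all genes and scores here), Abca3 (6.11), Cyp8b1 (5.63) and Slc37a4 (5.69). RPK;Pdk1 replicate 8 had the largest total (3320051), and stood apart in the pericentral score (3.57), the acinar score (7.39), Cela3b (7.70), Cpb1 (7.37), Cyp2e1 (5.25), Dusp5 (6.57), Hoxb2 (6.36), Nrf1 (8.88), Scd2 (8.49), Mmp8 (1.74) and mt-Co1 (10.14). RPK replicate 9 stood apart in the mitochondrial share (9.80%), mt-Co1 (10.24), mt-Nd5 (11.00) and Fstl1 (7.21).

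Other list scores far from their group were FOXO-induced genes in RPK;Pdk1 replicate 5 (5.87), cholesterol synthesis in RPK replicate 3 (5.54), immediate-early genes in RPK replicate 3 (6.02), antigen-presenting cell genes in RPK;Mek1/2 replicate 4 (6.83) and acinar markers in RPK;Mek1/2 replicate 2 (10.34), with Cela3b at 10.71 and Cpb1 at 10.65 in that library. Among control livers, replicate 4 was apart in A1bg (11.82), Acly (8.20), C1qb (7.37), Fgb (12.63), Spry2 (5.37) and Ube2c (4.29), replicate 2 in Cdh6 (3.49), Clec4g (6.94) and Epcam (6.58), and replicate 3 in Elovl6 (7.30). Among RPK tumors the values were Bub1 5.30, Ccnb1 5.83 and Gm6475 3.06 in replicate 7, Clec4g 4.94 and Fbp1 9.26 in replicate 3, Ltf 9.56 in replicate 1, Mup15 1.78 and Stat2 5.27 in replicate 2 and Spry2 5.11 in replicate 8. Among RPK;Pdk1 tumors they were Des 7.38 and Mafb 6.35 in replicate 6, and Gkn1 8.55, Tpsab1 8.45 and mt-Cytb 12.43 in replicate 5. Among RPK;Mek1/2 tumors they were Hnf4a 4.35, Msr1 7.37 and mt-Co1 10.06 in replicate 1, Insig1 4.96, Lox 4.51 and Sox9 9.05 in replicate 6 and Mafb 7.37 in replicate 3.

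Reads outside exons were not part of the comparisons of genes. Intergenic reads averaged 17.7% in RPK tumors, 16.0% in PDK1-deficient tumors and 23.2% in MEK-deficient tumors, above the highest control liver (13.38%). Intronic reads averaged 18.9% in RPK tumors and 20.3% in PDK1-deficient tumors, with each library above the highest control liver (11.95%), and 19.8% in MEK-deficient tumors, where replicate 5 (10.82%) was below it.

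Transcripts counted mostly in a single tumor library were also counted in the other tumor libraries, at a low level in most. Some levels were not low. Xist had 3423 CPM in RPK;Pdk1 replicate 8 and 1243 in RPK replicate 9, with a median of 46.5 over 20 other tumor libraries. Sftpa1 and Tpsab1, summed, had 2440 CPM in RPK;Pdk1 replicate 5 and up to 593 in another tumor library. For genes with at least 60% of their counts in 1 tumor library, summed by their 4 source libraries, the levels in 20 other tumor libraries rose and fell together (mean Spearman correlation 0.514, against a 95th percentile of 0.333 over 1000 sets of genes matched in level), so exchange of molecules between the barcodes of the pool may explain them. Expression by cells of each library stays open too. The lowest level in these libraries was under 1% of the source, the bound set for it before the test was run (median over the 4 sources 0.532%, lower 95% Poisson bound). That bound cannot decide between expression and exchange, since the exchange estimated below also gives single libraries under 1% of a gene's counts (0.330% in RPK replicate 2). A mixture of cells was not tested. Over 14 genes, a median of 32.1% of the counts lay outside the main library, a share bounded from above by the 60% rule. Exchange was estimated from the lower quartile, over these genes, of the share in each other library. These quartiles sum to 15.8%, so the estimate lies below the amount if all such counts were exchanged. By that estimate exchange would make up 36.4% of the counts in RPK;Mek1/2 replicate 5. The medians of exchange would be 13.3% in control liver, 16.6% in RPK, 13.6% in PDK1-deficient and 18.3% in MEK-deficient tumors. That would draw fold changes toward 0 and limit rises from a low level in control liver: among 5921 genes of average log2 CPM over 5, the highest 0.1% of RPK changes began at 2.43 and the lowest 0.1% at -6.07, with predicted ceilings of 3.11 and 4.47, and 5.90 and -8.01 after subtraction.

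Genes called in PDK1-deficient against RPK tumors lie near Pdpk1 in 3 of 4 cases (Abca3, Npw and Tpsab1, within 5 Mb). With the called genes left out, an unadjusted p under 0.05 was more frequent near Pdpk1 (18 of 146 genes) than elsewhere (899 of 13174), with an odds ratio of 1.92 (1.10 to 3.18, Fisher's exact test p = 0.0194), so variants or altered regulation linked to the targeted allele may account for part of them, though Tpsab1 rests on RPK;Pdk1 replicate 5 (1.39 without it). Near Map2k1 and Map2k2 the odds ratio was 0.920 (0.594 to 1.38, Fisher's exact test p = 0.767). This argues against an enrichment as large as 1.92 in MEK-deficient tumors. The test pools the genes near both loci, so it cannot tell whether single genes, such as Rplp1, differ through variants linked to a targeted allele. Rplp1 lies near Map2k1, and the sum of Rplp1, Gm11942 and Gm10073 fell by 223 CPM, 19.9% of the fall of Rplp1 alone, so reads assigned to Gm11942 in place of Rplp1 are a candidate explanation. Why the assignment would differ in all 7 MEK-deficient libraries was not tested, and an effect of PDK1 or MEK loss on these genes stays open.

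Mitochondrial transcripts and Nrf1, Hoxb2 and Map3k10 were higher in MEK-deficient than in RPK tumors. The mean intergenic share was also higher there, but that difference did not pass (exact permutation test, adjusted p = 0.147). It ran from 13.62% in RPK;Mek1/2 replicate 4 to 42.64% in replicate 5. With the intergenic share as a term the mean log2 fold change of the 7 mitochondrial genes stayed at 93.7% (1.23 to 1.15, 5 called), and without RPK;Mek1/2 replicate 5 at 94.9% (1.17, 6 called), which argues against either as the whole cause of that mean. Of its members mt-Nd5 went from 1.10 ± 0.22 to 1.04 ± 0.24 with the term (adjusted p = 0.0766, a wider error), and mt-Rnr1 from 1.17 ± 0.26 to 0.64 ± 0.20 (adjusted p = 0.210, a smaller change) and to 0.80 without replicate 5, so library quality stays open for mt-Rnr1. For Nrf1, Hoxb2 and Map3k10 the mean fell to 60.4% with the term (2.00 to 1.21, 0 of 3 called by edgeR), because the changes shrank, to 81.9% without replicate 5 (1.64, 2 called) and to 77.2% without the 2 shallowest RPK;Mek1/2 libraries (1.54, 0 called by edgeR), so library quality may account for part of them. Other measures of quality and the deficiency itself stay open.

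Other splits of the libraries into groups of the same sizes, 100 per comparison with the real one, tested whether chance gives as many genes. For RPK, MEK-deficient and PDK1-deficient tumors against control liver, only the real split gave as many genes (6021, 6636 and 5894, against 2727, 3309 and 2867 at most in the others). That share, 1 of 100, is the lowest this test can give. For MEK-deficient against RPK tumors 2 of 100 splits gave 40 genes or more, with 218 the highest other. For PDK1-deficient against RPK tumors 3 of 100 gave 4 or more, with 442 the highest other, and between the deficient groups 2 of 100 gave 64 or more, with 744 the highest other. These shares lie under the 5% bound set before the test, but they come from 100 splits and were not adjusted over comparisons. They argue against chance without excluding it. In each of the 3 comparisons between tumor groups 1 other split called several times the real count (the next highest gave 25, 5 and 37). That points to a structure of the samples other than the groups. These splits did not part the barcode sets (AT-rich libraries were 5 of 7 against 3 of 9, 4 of 8 against 4 of 9, and 5 of 7 against 3 of 8 on the sides). Among the 99 other splits, those of 218 and 442 genes had the widest gap between their sides on the first principal component. That of 744 genes had it on the second, so these splits part the libraries along the leading axes of variation. The first component parts control liver (-128 to -104) from tumors (-32.1 to 54.6). The splits of 218 and 442 genes thus set tumors nearer to control liver against the others (means 5.22 against 32.7, and 2.60 against 29.4). What underlies these axes among tumors stays open.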

How the results depend on the processing

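Chosen after seeing the data were the settings without the 2 shallowest RPK;Mek1/2 libraries, without mitochondrial genes and CT010467.1, without the 3 libraries low in Y-linked genes, with the estimated exchange between barcodes subtracted and with the intergenic share as a term. Unless stated, the cause was not tested. For genes against control liver, each total stayed within 1.5 times its value in every setting run, leave-one-out included. The numbers of higher genes moved more: from 2928 to 1745 and 1654 for RPK tumors and from 3484 to 2192 and 2079 for MEK-deficient tumors without control liver replicates 2 and 3. For PDK1-deficient tumors 2959 became 1891, 1571, 1530 and 1836 without control liver replicates 1 to 4, and 1744 without the 3 libraries low in Y-linked genes. Control comparisons have no value with GC-rich barcodes alone, for lack of control libraries.

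Counts between tumor groups depended on the processing. For MEK-deficient against RPK tumors the 40 genes became 77 without a count filter, 2 with AT-rich and 1 with GC-rich barcodes alone (fewer samples), 19 without the RPK libraries lacking the reporter, 24 with only the groups compared and 97 by DESeq2. They became 16 without the 2 shallowest RPK;Mek1/2 libraries, 154 without the 3 libraries low in Y-linked genes and 13 with the intergenic share as a term. For PDK1-deficient against RPK tumors the 4 genes became 2 with DESeq2 size factors, 2 with a robust fit, 28 without a filter, 2 with the barcode set as a term, and 1 with AT-rich barcodes. They became 0 by edgeR with GC-rich ones (837 at an unadjusted p under 0.05), 1 without the RPK libraries lacking the reporter, 1 with only the groups compared, 30 by DESeq2, 7 by voom and 2 without mitochondrial genes and CT010467.1. Between the deficient groups the 64 genes became 99 without a filter, 38 with a replicate block, and 2 with AT-rich and 3 with GC-rich barcodes. They became 22 with only the groups compared, 135 by DESeq2, 22 without the 2 shallowest libraries, 217 without the 3 low in Y-linked genes, 42 with exchange subtracted and 18 with the intergenic term.

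Leaving out 1 library gave 4611 to 6202 genes for RPK tumors against control liver, 5115 to 6838 for MEK-deficient and 4361 to 6037 for PDK1-deficient tumors. Between tumor groups it gave 21 to 116 for MEK-deficient against RPK (21 without RPK replicate 6, 22 without 8, 24 without 3, 62 without 2, 74 without 9, 78 without RPK;Pdk1 replicate 8, 113 and 116 without RPK;Mek1/2 replicates 1 and 4). For PDK1-deficient against RPK it gave 2 to 7 (7 without RPK;Pdk1 replicate 7, and 2 without each of control liver replicates 1 to 3, RPK replicates 1 and 3 to 8 and RPK;Mek1/2 replicates 1 to 4, 6 and 7). Between the deficient groups it gave 31 to 188 (31 without RPK;Mek1/2 replicate 3, 116 without 4, 40, 38, 42, 41 and 40 without RPK;Pdk1 replicates 1 to 5, and 188 without 8).

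The biliary, hepatocyte and ERK lists kept direction and call against control liver in each setting but the estimated correlation, where adjusted p became 0.397, 0.200 and 0.104 for RPK tumors. Of 86 list calls 83 ended with it. The neutrophil call for PDK1-deficient against RPK tumors held in 16 of 16 settings and 28 of 28 leave-one-out fits.

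For PDK1-deficient against RPK tumors the biliary list passed, higher, with a replicate block (adjusted p = 0.0285), GC-rich barcodes alone (0.000372), voom (0.00312) and without the 3 libraries low in Y-linked genes (0.00735), with 0.00429 to 0.809 over leave-one-out fits and 0.964 without the RPK libraries lacking the reporter. The hepatocyte list passed, lower, with a block (0.0235) and GC-rich barcodes (1.94e-05), and ranged from 0.00314 to 0.928 over leave-one-out fits. The ERK list ranged from 0.0429 to 0.720. For MEK-deficient against RPK tumors the biliary list passed, higher, with AT-rich barcodes (0.000344), and the hepatocyte call ended with voom (0.0981), an estimated correlation (0.759) and exchange subtracted (0.0850), with 8.35e-05 to 0.475 over leave-one-out fits. Between the deficient groups the hepatocyte list ranged from 0.00526 to 0.944.

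Directions reversed within barcode sets alone, which hold fewer samples. Some lists were called in opposite directions with AT-rich and with GC-rich barcodes, so fewer samples are not shown to be the cause, which was not tested. List calls between tumor groups thus depend on which libraries are compared. With AT-rich barcodes, MEK-deficient against RPK tumors had hepatocyte markers higher (adjusted p = 0.0733) and acinar markers lower (0.987). PDK1-deficient tumors had higher hepatocyte (0.00505), bile acid (0.211), urea cycle (0.0439), gluconeogenesis (0.00505), periportal (0.0475), interferon (0.825) and Kupffer cell (0.286) lists than RPK tumors. Between the deficient groups biliary markers were higher (8.76e-06) and acinar markers lower (0.0232) in MEK-deficient tumors, and with GC-rich barcodes they were lower (2.49e-07) and higher (0.00120). The ERK list passed there, higher, with AT-rich barcodes (0.0210). With GC-rich barcodes, biliary markers were lower (6.07e-05) and division genes higher (0.00240, but lower with AT-rich ones, 2.50e-05) in MEK-deficient than in RPK tumors, and division (0.0386) and antigen-presenting cell genes (0.00789) were higher in PDK1-deficient than in RPK tumors. Between the deficient groups macrophage markers were higher (0.0497) and antigen-presenting cell genes lower (0.0471).

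ERK score differences from control liver fell from 0.96, 0.88 and 0.99 to 0.70, 0.64 and 0.73 with a pseudocount of 10, which shrinks log values. The correlation between the comparisons that share RPK libraries became 0.110 with those libraries split.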

Other observations

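Markers of liver sinusoidal and other endothelial cells differed between tumors and control liver. In RPK tumors 2 of 21 were higher and 8 lower (2 and 8 adjusted over the list alone, median log2 fold change -0.72, camera adjusted p = 0.0434, and adjusted p = 0.544 with an estimated correlation). Clec4g and Dnase1l3, both expressed by sinusoidal endothelium, fell by 3.71 ± 0.51 and 3.66 ± 0.52. The call in RPK tumors was lost without control liver replicate 2 or 4 (adjusted p = 0.0541 and 0.110) or RPK replicate 2, 5, 7 or 9 (adjusted p = 0.0534, 0.0659, 0.0624 and 0.0635). It was also lost with DESeq2 size factors (adjusted p = 0.0511), a replicate block (adjusted p = 0.0821), voom (adjusted p = 0.0800), without the RPK libraries lacking the reporter (adjusted p = 0.0546) and without the 3 libraries low in Y-linked genes (adjusted p = 0.141). The list was also lower in MEK-deficient tumors (adjusted p = 0.00359) and in PDK1-deficient tumors (adjusted p = 0.00195), with adjusted p = 0.422 and 0.421 with an estimated correlation.

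Oncofetal liver genes rose in RPK tumors (6 of 14, 6 adjusted over the list alone, median 0.96, adjusted p = 0.0402, and adjusted p = 0.178 with an estimated correlation). Igf2bp2, an RNA-binding protein of fetal liver, rose by 1.70 ± 0.41 and the desaturase gene Scd2 by 0.99 ± 0.30, a call lost without control liver replicate 3 (0.84). The list call was lost without RPK replicate 2 (adjusted p = 0.0568) or 9 (adjusted p = 0.0539), with AT-rich barcodes alone (adjusted p = 0.0717) and with the intergenic share as a term (adjusted p = 0.0637). The list also rose in MEK-deficient tumors (7 of 14, adjusted p = 0.0318, and adjusted p = 0.0509 without RPK;Mek1/2 replicate 5) and PDK1-deficient tumors (8 of 14, adjusted p = 0.0222). With an estimated correlation these had adjusted p = 0.186 and 0.142. The call in MEK-deficient tumors was lost without the 2 shallowest RPK;Mek1/2 libraries (adjusted p = 0.0602) and with the intergenic term (adjusted p = 0.0794).

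Kupffer cell markers, of the resident liver macrophages, were lower in PDK1-deficient tumors (3 of 9, adjusted p = 0.018) and in MEK-deficient tumors (4 of 9, adjusted p = 0.0318) than in control liver. These calls were lost with an estimated correlation (adjusted p = 0.393 and 0.422) and without the 3 libraries low in Y-linked genes (adjusted p = 0.0543 and 0.0606). In RPK tumors 3 of 9 were lower (3 adjusted over the list alone, adjusted p = 0.0894, and adjusted p = 0.00890 with AT-rich barcodes alone). Erythroid markers were lower in the same pair of groups (5 of 7, adjusted p = 0.014, and 6 of 7, adjusted p = 0.0239), with 4 of 7 lower in RPK tumors (4 adjusted over the list alone, adjusted p = 0.0667). The erythroid calls were lost with an estimated correlation (adjusted p = 0.390 and 0.417) and without the 3 libraries low in Y-linked genes (adjusted p = 0.0676 and 0.0606). Glycolysis and hypoxia genes were higher in MEK-deficient tumors (13 of 20, with 1 lower, adjusted p = 0.0318), as were immediate-early genes (7 of 15, adjusted p = 0.0392), and acute-phase genes were lower (9 of 19, with 1 higher, adjusted p = 0.028). With an estimated correlation these 3 had adjusted p = 0.502, 0.317 and 0.593. In MEK-deficient tumors the Kupffer cell and erythroid calls were lost without control liver replicate 4 (adjusted p = 0.0582 each), as was the acute-phase call (adjusted p = 0.0604). The glycolysis call was lost without RPK;Mek1/2 replicate 5 (adjusted p = 0.0502). The immediate-early call was lost without control liver replicate 1 (adjusted p = 0.0620) or RPK;Mek1/2 replicate 3 or 5 (adjusted p = 0.0762 and 0.0509), and with the barcode set as a term (adjusted p = 0.0506). The glycolysis and immediate-early calls were also lost without the 2 shallowest RPK;Mek1/2 libraries (adjusted p = 0.0780 and 0.108) and with the intergenic term (adjusted p = 0.0927 each).

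In RPK tumors against control liver, 8 glycolysis and hypoxia genes were higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.0582) and 5 of 15 immediate-early genes were higher (5 adjusted over the list alone, adjusted p = 0.0753). Among 20 gastrointestinal mucin and trefoil genes 5 were higher and none of them adjusted over the list alone (median 1.57, adjusted p = 0.0894). The p53 target genes went both ways (6 higher and 5 lower of 17, 7 and 5 adjusted over the list alone, median -0.03 with an upward camera sign, adjusted p = 0.915). Acute-phase genes gave 4 higher and 5 lower of 19 (4 and 5 adjusted over the list alone, adjusted p = 0.295). Interferon-stimulated genes gave 1 higher and 1 lower of 20 (1 and 0 adjusted over the list alone, adjusted p = 0.736), and unfolded protein response genes 6 lower of 15 (5 adjusted over the list alone, adjusted p = 0.219). Lists of T and NK cell, B and plasma cell, mesothelial and adipocyte markers had 3 tested members each and were not tested.

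The score of pancreatic acinar markers was 4.56 ± 0.17 (SD, n = 4) in control liver, 3.92 ± 0.81 (n = 9) in RPK tumors, 4.11 ± 1.43 (n = 8) in PDK1-deficient tumors and 4.92 ± 2.51 (n = 7) in MEK-deficient tumors. RPK;Mek1/2 replicate 2 was at 10.34 and RPK;Pdk1 replicate 8 at 7.39. In RPK tumors 1 of 7 of these markers was lower than in control liver (1 adjusted over the list alone, adjusted p = 0.492).

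Y-linked genes were at 17.2 CPM in RPK;Pdk1 replicate 8, at 45.2 in RPK replicate 9 and at 32.3 in control liver replicate 4. The X-inactivation transcript Xist was at 3423 CPM in RPK;Pdk1 replicate 8 and at 1243 in RPK replicate 9, and at 102 in control liver replicate 4. The sex of the mice is not given in the labels.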
